A study of Mus musculus with 19 samples.

How the data were processed

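The series measured gene expression in CD4+ T cells sorted from the spleen or liver of C57BL/6J mice, either naive or infected with Leishmania donovani for 56 days. It holds 19 arrays: 5 of naive spleen, 5 of infected spleen, 4 of naive liver and 5 of infected liver. Per the labels, each naive liver sample was a pool from 5 mice. Cells were sorted into a lysis buffer, and biotinylated cRNA was hybridized to Illumina MouseWG-6 v2 arrays, per the labels' protocols. The arrays sat on 4 chips. Chip 4 held only the infected spleen sample 5, and the other 3 chips held samples of all 4 groups.

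Per the file headers, the deposited probe table was exported from GenomeStudio 1.6.0 and gives each probe's intensity on a linear scale, without normalization. The deposited table also holds a detection column per array, which per the file headers is a detection value and by its values equals 1 minus the detection p-value. The authors also deposited a normalized matrix of 22101 probes, made with lumi per the submitters' processing notes, which give no version. By its values the authors' matrix is on a log2 scale, centred per probe on a reference that stays unknown. Its columns had medians of -0.02236 to 0.01593. Of its probes, 21977 were matched to the probe table by their values, because its own probe numbers did not belong to its values. Only 1 of the matched probes carried the number of the probe that its values matched. The matrix was used as an alternative only. By its values, differences in the matrix are about 0.792 of the log2 differences, and the cause of this was not tested. The probe table contains 5 array columns that no sample of the series claims, and these were used in no step.

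The intensities were background-corrected, quantile-normalized and put on a log2 scale with neqc of limma 3.58.1 (R 4.3.3, package data.table, version 1.17.8), with an offset of 16 and the background taken from the detection p-values. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with numpy 2.4.6. Of 45281 probes, 19391 had a detection p under 0.05 on at least 4 arrays and were kept. Probes were named from the file's own gene names, updated through a table of symbols and synonyms. Of all probes, 27760 matched a current symbol, 8035 matched through a synonym, 187 had a synonym shared by several genes, and 9299 kept the file's name. The last group includes unnamed transcripts. Where several probes shared a gene, the probe with the highest mean over the 19 arrays was tested, which left 13206 genes. Other probes of named genes are given where they moved much less or in the other direction.

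The number of probes at detection p under 0.05 ranged from 12791 to 18031 per array. Within groups, the correlation of log2 values between arrays was 0.862 to 0.984 in naive spleen, 0.827 to 0.979 in infected spleen, 0.987 to 0.993 in naive liver and 0.932 to 0.989 in infected liver, and 0 pairs of arrays were identical. Detected probes, median signal and spread were compared between groups with exact permutation tests, 2-sided, whose smallest possible p at 5 against 5 arrays is 0.00794.

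A linear model with 4 group means was fitted to all 19 arrays with lmFit and eBayes of limma. It gave 5 comparisons: infected against naive in spleen and in liver, liver against spleen in naive and in infected mice, and the difference of the infection effects (liver minus spleen). P-values were 2-sided and adjusted over all 13206 genes by the method of Benjamini and Hochberg, with adjusted p under 0.05 as the threshold. Error terms are standard errors of the log2 difference from this fit. Where the tested probe was detected on no array of the dimmer group, or that group's mean lay below the mean over its arrays of the lowest signal of a detected probe (log2 4.93 to 5.43), the fold is a bound and the group is said to be at background. Detection of a gene on an array is that of the tested probe. The bound sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the lowest signal of a detected probe or the probe's own level, whichever was higher. The labels number the samples without saying which animals they came from outside naive liver, so p-values measure the spread between these samples, and the number of arrays limits their precision.

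There were 18 gene lists and 13 lists of cell type markers, fixed before the data were examined. Lists of at least 5 measured genes were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the 29 lists tested in each comparison. Camera with an estimated correlation and fry were run beside it. The CD8 T cell and gamma delta T cell markers had 4 measured genes each and were not tested. Counts of list members past the threshold are adjusted over all genes unless they are given as adjusted over the list alone.

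Named genes followed a rule that was also fixed before the data were examined. For each of the first 4 comparisons it takes the 8 largest increases and 8 largest decreases among genes past the threshold whose groups did not overlap, leaving out unnamed transcripts and immunoglobulin and T cell receptor segments. For the difference of the infection effects it takes 6 in each direction. It adds fixed sets of immune genes for infection and for organ, and up to 4 members with the smallest p of each list described. Gzmb was detected on 1 array and was therefore not tested. Some genes that the rule names are not reported here.

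Alternatives fixed before the data were examined were the authors' matrix, no background correction, cyclic loess scaling, no filter, a stricter filter (detection p under 0.01 on at least 9 arrays), the mean of a gene's probes, only the groups compared, the sample number as a block, the chip as a block, moderation with trend and robust, array weights, and leaving out each array. For each comparison, 100 splits of its arrays into groups of the same sizes, the real grouping included, were also tested. After seeing the data, 3 alternatives were added because arrays differed in quality. The first was an array score as a covariate, namely the first principal component of each probe's deviation from the mean of its gene's detected probes, over 10400 probes of 4215 genes. The others left out the 5 or the 9 arrays with the fewest detected probes.

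The scripts were tested on simulated data for 13206 genes with 50 changed genes of each size, with noise either independent between genes or with a component shared within arrays. At a log2 change of 2.00 they called 92% and 96% of the changed genes for infection in spleen, 88% and 82% for infection in liver, 88% and 86% for naive organs, 88% and 90% for infected organs, and 68% and 52% for the difference of the effects. At a log2 change of 1.00 the shares were 58% and 50%, 42% and 40%, 46% and 48%, 56% and 52%, and 34% and 16%. Genes of smaller change are therefore often missed, most of all in the difference of the effects.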

Results

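Infection raised genes in splenic CD4+ T cells, some of which were below detection in naive cells. Rasd2, which encodes a GTP-binding protein of the Ras family, was detected on 0 of 5 naive arrays and rose at least 41.3-fold (log2 5.99 ± 0.16, n = 5 and 5, adjusted p = 1.55e-14). Ifng, the gene of the cytokine that arms macrophages against the parasite, rose 19.6-fold (log2 4.30 ± 0.18, adjusted p = 1.44e-11), from a mean log2 level of 8.69 (SD 0.48) to 12.99 (SD 0.12). Serpina12, which encodes a serine protease inhibitor, rose at least 35.9-fold (log2 5.98 ± 0.22, adjusted p = 1.21e-12). The long non-coding RNA Miat rose at least 23.8-fold (log2 5.49 ± 0.28, adjusted p = 2.04e-10).

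Genes of receptors such as Cx3cr1 and S1pr5 were also among the largest increases in spleen. Cx3cr1, the fractalkine receptor, rose 29.5-fold (log2 4.88 ± 0.31, adjusted p = 3.45e-09), and S1pr5, a sphingosine phosphate receptor, rose at least 14.5-fold (log2 4.58 ± 0.26, adjusted p = 6.08e-10). The immunoglobulin-like receptor genes Lilr4b and Lilrb4a rose at least 19.4-fold (log2 5.13 ± 0.43, adjusted p = 1.10e-07) and at least 15-fold (log2 4.72 ± 0.25, adjusted p = 3.95e-10). The chemokine gene Ccl4 rose 25.6-fold (log2 4.68 ± 0.27, adjusted p = 8.18e-10), and the cytokine gene Il21 rose 15.2-fold (log2 3.93 ± 0.46, adjusted p = 6.30e-06). Second probes moved less for Serpina12 (log2 1.58), Miat (0.20), Lilrb4a (2.09) and S1pr5 (2.00).

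Aqp9, which encodes a water and glycerol channel, fell most among the genes named in spleen, at least 8.65-fold (log2 -3.54 ± 0.19, adjusted p = 3.95e-10), to detection on 1 of 5 infected arrays. Cd163, the macrophage scavenger receptor for haemoglobin, fell at least 3.93-fold (log2 -2.81 ± 0.21, adjusted p = 2.23e-08). Log2 decreases between -2.69 and -2.36 were found for Tmem273 (-2.69 ± 0.36, adjusted p = 2.73e-05), Grm6 (-2.43 ± 0.25, 1.77e-06), Xkrx (-2.41 ± 0.15, 3.45e-09), Adh1 (-2.39 ± 0.25, 1.81e-06), Ttc28 (-2.37 ± 0.25, 1.80e-06) and Ampd1 (-2.36 ± 0.17, 1.75e-08). Infected samples detected Grm6 on 1 array (at least 3.9-fold lower), Adh1 on 2 (at least 4.08-fold) and Xkrx on 4. Other probes moved less for Tmem273 (log2 -0.11) and Adh1 (-0.52).

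Among genes of helper T cell function chosen in advance, Nkg7, Ccl5, Cxcr6 and Il10 rose in spleen and Ccr7 fell. Nkg7, a protein of cytotoxic granules, rose 7.36-fold (log2 2.88 ± 0.34, adjusted p = 6.30e-06), Ccl5 rose 3.28-fold (1.71 ± 0.12, 1.75e-08), Cxcr6 2.42-fold (1.27 ± 0.23, 0.000638) and Il10 at least 2.36-fold (1.55 ± 0.33, 0.00250). The lymph node homing gene Ccr7 fell 2.31-fold (log2 -1.21 ± 0.26, adjusted p = 0.00289). Tbx21, the master regulator of Th1 cells, rose 4.39-fold (log2 2.13 ± 0.53, adjusted p = 0.00974) with overlapping groups. Its log2 differences within chips were 3.46, 4.30 and -0.46, and the call was lost when only the spleen groups were fitted (adjusted p = 0.0961). The Il10 call was lost without the 5 (adjusted p = 0.143) or 9 (0.0816) arrays with the fewest detected probes. Foxp3 (log2 -0.46 ± 0.15, adjusted p = 0.0542) and Pdcd1 (0.15 ± 0.25, 0.841) were not past the threshold. Foxp3 passed it with array weights (adjusted p = 0.00756), the array score (0.00856), the authors' matrix (0.0193), no background correction (0.0192), loess scaling (0.0207) and a stricter filter (0.0432). It also passed without spleen naive 2 (0.0295), spleen infected 1 (0.0431), spleen infected 4 (0.0329) or liver infected 4 (0.0354).

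As groups, cell cycle, interferon gamma response and Th1 effector genes had the smallest p-values among lists that rose in spleen. Th1 effector genes rose (median log2 1.37, adjusted p = 1.82e-13), with 12 of 20 members higher and 0 lower, such as Ifng, Ccl4 and Ccl5. Adjusted over the list alone, 14 were higher and 1 lower. Cell cycle genes rose (median log2 1.46, adjusted p = 6.79e-21), with 20 of 30 higher and 0 lower, among them the mitotic genes Ccnb1 (log2 2.72), Birc5 (2.62), Tpx2 (2.55, at least 4.05-fold, detected on 1 naive array) and Aurka (2.06). Of 27 genes of the interferon gamma response, 16 rose and 0 fell (median 0.80, adjusted p = 3.02e-15), for instance Serpina3g (2.83), Gbp3 (2.40) and Gbp2 (1.75, another probe 0.61). Chemokine receptor and adhesion genes rose (median 0.70, adjusted p = 0.00108), 6 of 18 higher and 2 lower. Naive T cell and lymphoid homing genes fell (median -1.19, adjusted p = 1.09e-11), 13 of 20 lower and 0 higher, such as Il7r (-1.03, adjusted p = 0.0924 without the 9 arrays with the fewest detected probes), Il6ra (-2.28, other probes -0.43 and -0.96) and Sox4 (-2.16, another probe -0.14). Adjusted over the list alone, 17 of them were lower.

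Smaller group shifts in spleen depended more on the correlation between genes. Genes of IL-10 producing cells and inhibitory receptors rose (median log2 0.28, adjusted p = 0.00221, and 0.118 with an estimated correlation), with 7 of 16 higher and 3 lower. Higher members were Havcr2 (log2 3.47 ± 0.25, at least 9.35-fold), Lag3 (2.86 ± 0.28), Il21 and the transcription factor gene Maf (1.49 ± 0.21, detected on 2 naive arrays). Tissue residency genes rose (median 0.80, adjusted p = 0.000737, and 0.113 with an estimated correlation), 9 of 17 higher and 3 lower, such as Bhlhe40 (3.76) and Rgs1 (1.91). Cytotoxic genes rose (median 0.90, adjusted p = 0.0229, and 0.0724 with an estimated correlation), 8 of 16 higher and 3 lower. Gzmm (1.68) and Cst7 (2.01) rose, while the killer receptor gene Klrk1 fell at least 2.29-fold (log2 -2.00, other probes 0.01 and -0.16). Without the sample spleen infected 2 the adjusted p of the cytotoxic genes was 0.0536. Glycolysis genes rose (median 0.60, adjusted p = 0.00108, and 0.263 with an estimated correlation), but only 3 of 18 members passed alone, including Tpi1 (1.80, another probe 0.48) and Gapdh (0.75). Their medians within chips were 1.08, 1.58 and -0.62.

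Among marker lists of other cell types, those of dendritic and plasma cells rose in spleen, but several of their members were not measured. The dendritic cell genes Itgax, Flt3 and Xcr1 and the plasma cell genes Jchain, Sdc1, Derl3 and Tnfrsf17 were below the filter. The lists therefore do not show that these cells were present. Dendritic cell markers rose (median log2 0.70, adjusted p = 0.00108), 4 of 13 higher and 0 lower, with the class II regulator gene Ciita at log2 1.63 ± 0.23 (at least 1.94-fold, adjusted p = 5.39e-05, detected on 1 naive array) and the class II genes H2-Eb1 at 1.55 ± 0.36 (0.00575) and H2-Ab1 at 1.09 ± 0.26 (0.00678). The class II calls were lost with only the spleen groups fitted (adjusted p = 0.0659 for H2-Eb1 and 0.0624 for H2-Ab1), and H2-Ab1 also with the mean of its probes (0.206) and without the 5 (0.0759) or 9 (0.113) arrays with the fewest detected probes. Ciita was lost without the 9 arrays (0.116). Plasma cell markers rose (median 0.53, adjusted p = 0.0272, and 0.118 with an estimated correlation), 1 of 5 higher, namely Xbp1 (0.68). Their adjusted p was 0.0633 without spleen naive 2, 0.0605 without spleen naive 4 and 0.0613 without spleen infected 4. Markers of B cells (median -0.02, adjusted p = 0.860), macrophages (-0.04, 0.758), neutrophils (0.28, 0.347), NK cells (-0.12, 0.272), erythroid cells (0.32, 0.247), hepatocytes (-0.05, 0.646) and endothelium (0.19, 0.287) were not past the threshold, nor were T cell identity genes (0.12, 0.463). NKT cell markers were mixed, with 5 of 13 higher and 5 lower (median -0.17, adjusted p = 0.808), and their test leaned to higher values.

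Lists not past the threshold in spleen were regulatory T cells (median log2 0.27, adjusted p = 0.247), Th17 (1.5, 0.229), Th2 (-0.32, 0.808), type I interferon (-0.01, 0.385), oxidative phosphorylation (0.06, 0.183), cholesterol synthesis (-0.40, 0.0682), immediate early and heat shock genes (-0.09, 0.860) and ribosomal proteins (-0.10, 0.247). Cholesterol synthesis passed with loess scaling (adjusted p = 0.0257), no filter (0.0149), the array score (0.0335), without the 9 arrays with the fewest detected probes (0.00658), and without spleen naive 1 (0.0462), 3 (0.0359) or 5 (0.0444) or spleen infected 2 (0.0271) or 3 (0.0335). Follicular helper genes had a median of -0.26, while their test leaned to higher values (adjusted p = 0.808). In all, 1745 of 13206 genes changed in spleen (854 higher, 891 lower), 877 of them at least 2-fold and 1105 without overlap of the groups. Of all genes, 1224 (9.3%) had groups without overlap, against 0.794% by chance. The unadjusted p was under 0.05 for 3089 genes. The count was 1026 with only the spleen groups fitted, 3215 with array weights and 3773 with the array score.

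**Figure D1:**
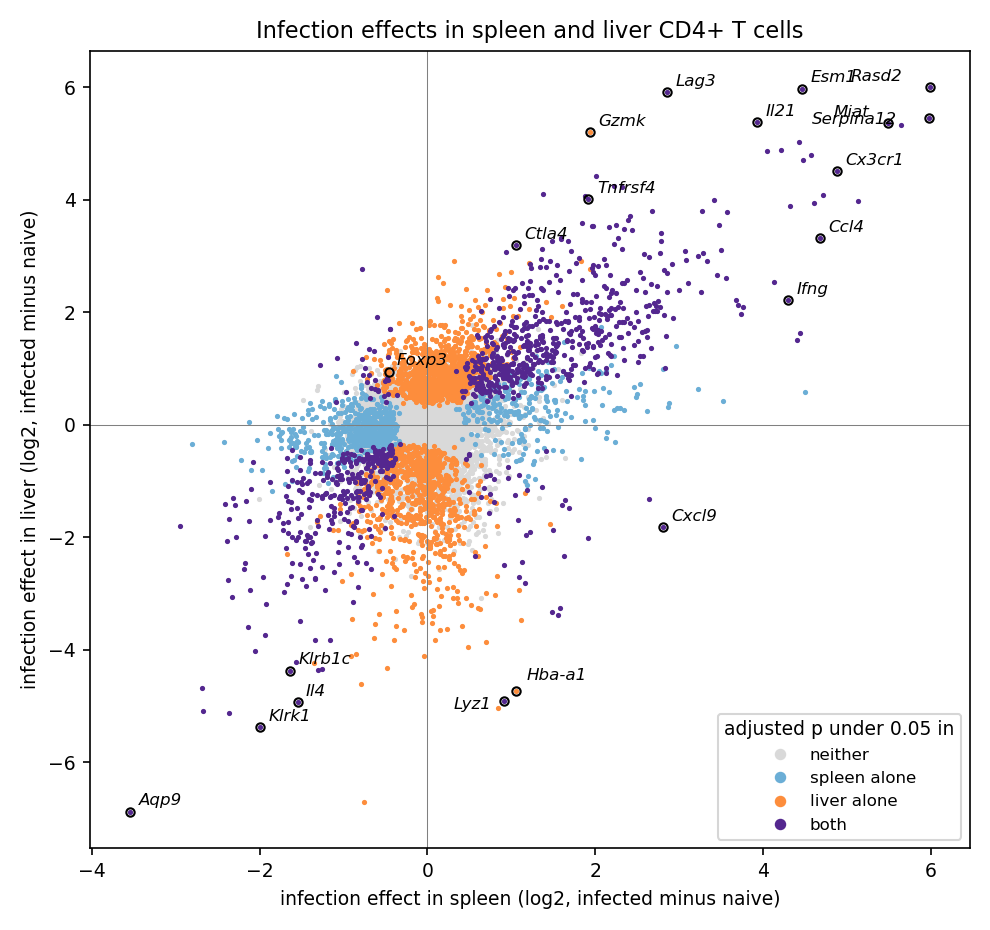
Log2 change with infection in spleen (horizontal) and liver (vertical) for all tested genes, coloured by where the change was past an adjusted p of 0.05.

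Several of the largest increases in liver, such as that of Rasd2, were of genes that also rose in spleen. Rasd2, detected on 0 of 4 naive arrays, rose at least 52.4-fold (log2 6.01 ± 0.17, n = 5 and 4, adjusted p = 4.18e-14). Lag3, an inhibitory receptor that binds class II molecules, rose 60.3-fold (log2 5.91 ± 0.30, adjusted p = 8.21e-11), and Esm1, which encodes a secreted proteoglycan, rose at least 49.5-fold (log2 5.98 ± 0.36, adjusted p = 6.75e-10). Il21 rose at least 38.8-fold (log2 5.39 ± 0.49, adjusted p = 1.58e-07) and was detected on 2 naive arrays. Ifng rose 4.63-fold (log2 2.21 ± 0.19, adjusted p = 1.07e-07), from an already high level of 11.03 (SD 0.13) to 13.24 (SD 0.17).

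Further increases in liver were Serpina12 (at least 40.5-fold, log2 5.46 ± 0.23, adjusted p = 9.55e-12, 1 naive array detected, another probe 0.80), Miat (at least 33-fold, 5.37 ± 0.30, 2.57e-10, another probe 0.57), the granzyme gene Gzmk (5.21 ± 0.98, 0.000706) and Car5b, a mitochondrial carbonic anhydrase gene (at least 28.5-fold, 5.03 ± 0.20, 5.66e-12). Among decreases, Aqp9 fell at least 88.1-fold (log2 -6.88 ± 0.20, adjusted p = 5.60e-14) and the activating killer receptor gene Klrk1 at least 31.9-fold (-5.37 ± 0.18, 2.55e-13). The lysozyme genes Lyz2 (log2 -5.03 ± 0.45, adjusted p = 1.37e-07) and Lyz1 (-4.91 ± 0.27, 2.10e-10), the alpha-globin gene Hba-a1 (-4.73 ± 0.54, 3.08e-06) and Il4, a cytokine gene of Th2 and NKT cells (-4.94 ± 0.52, 9.67e-07), fell as well. Tmem273 (log2 -4.68 ± 0.38, adjusted p = 3.90e-08, another probe -1.46) and the adhesion receptor gene Adgrg5 (-4.61 ± 0.40, 9.34e-08) followed. Other probes of Lyz2 (-1.02 and -6.19) and Lyz1 (-0.08 and -0.48) moved unevenly.

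Foxp3, Il10, Ccl5 and Pdcd1 rose in liver among the genes chosen in advance. Foxp3, the defining transcription factor of regulatory T cells, rose 1.93-fold (log2 0.95 ± 0.16, adjusted p = 0.000274; other probes 1.84, 0.03 and 1.86), and Il10 rose at least 4.28-fold (2.36 ± 0.34, 5.10e-05). Ccl5 rose 1.43-fold (log2 0.51 ± 0.13, adjusted p = 0.00842), a call lost with loess scaling (0.0799). Ccr7 (log2 -0.77 ± 0.27, adjusted p = 0.0520), Cxcr6 (-0.63 ± 0.24, 0.0736), Nkg7 (0.38 ± 0.36, 0.505) and Tbx21 (-0.23 ± 0.56, 0.815) were not past the threshold. Pdcd1, the gene of an inhibitory receptor, rose at least 1.74-fold (log2 0.90 ± 0.27, adjusted p = 0.0221). That call was lost with the chip as a block (0.0525) and without liver naive 3 (0.0621), liver naive 4 (0.0712), liver infected 2 (0.0604) or liver infected 5 (0.0590). Ccr7 passed with loess scaling (adjusted p = 0.0111), a stricter filter (0.0480), trend and robust moderation (0.0458), array weights (0.000320), the array score (0.00199), only the liver groups (0.0181) and without the 5 (0.0236) or 9 (0.000810) arrays with the fewest detected probes. It also passed without spleen infected 2 (0.0488), 3 (0.0231) or 4 (0.0237) or liver infected 2 (0.0304). Cxcr6 passed with the chip as a block (0.0361), array weights (0.0168), only the liver groups (0.0249) and without the 5 arrays with the fewest detected probes (0.0413), spleen infected 4 (0.0472) or spleen infected 5 (0.0422). Nkg7 passed with the array score (0.00580), only the liver groups (0.0398) and without the 9 arrays (0.0283).

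By group, regulatory T cell genes rose in liver (median log2 0.92, adjusted p = 0.00283), 8 of 15 higher and 2 lower. Tnfrsf4, a costimulatory receptor gene, was at 4.01 ± 0.20, Klrg1 at 4.24 ± 0.46 and the inhibitory receptor gene Ctla4 at 3.20 ± 0.22. Cell cycle genes rose (median 1.13, adjusted p = 1.77e-07), 17 of 30 higher and 0 lower, such as Rrm2 (2.53), Ccnb1 (2.11) and Tpx2 (1.66, detected on 3 naive arrays). Genes of IL-10 producing cells and inhibitory receptors rose (median 0.94, adjusted p = 0.00286, and 0.112 with an estimated correlation), 9 of 16 higher and 2 lower, with Havcr2 at 3.55 and Btla at -2.36. Th1 effector genes rose (median 0.62, adjusted p = 0.0281, and 0.106 with an estimated correlation), 9 of 20 higher and 1 lower, including Ccl4 (3.32), Il18r1 (2.24, another probe 0.42) and Eomes (1.55, at least 2.42-fold). Their adjusted p was 0.0608 without liver infected 3. Interferon gamma response genes rose (median 0.25, adjusted p = 0.0197, and 0.105 with an estimated correlation), 7 of 27 higher and 0 lower, with Gbp3 at 1.64. Immediate early and heat shock genes rose (median 0.57, adjusted p = 0.0297, and 0.169 with an estimated correlation), 7 of 25 higher and 2 lower, with Jun at 2.25 and Fos at 1.32. Without liver infected 4 their adjusted p was 0.0774.

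Type I interferon response genes fell in liver (median log2 -0.48, adjusted p = 0.000142), 8 of 24 lower and 0 higher, among them Oas2 (-2.57, at least 4.88-fold, detected on 1 infected array), Oasl1 (-2.27, at least 3.89-fold) and Ifit3 (-1.97, another probe -0.96). Naive T cell and homing genes fell (median -0.83, adjusted p = 1.98e-05), 9 of 20 lower and 1 higher, such as the chromatin organizer gene Satb1 (-1.52). Sox4 was also lower (at least 1.86-fold, -1.36 ± 0.24, adjusted p = 0.000462), but its other probe was at 0.58 and the mean of its probes was not past the threshold (-0.39, 0.185).

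Cell type markers carried the clearest losses of liver infection. All 11 NK cell markers fell (median log2 -2.54, adjusted p = 1.07e-13), among them the receptor genes Klrb1c (-4.37 ± 0.22), Klre1 (-3.83 ± 0.38) and Fcer1g (-4.10 ± 0.20). Of 13 NKT cell markers, 9 fell and 1 rose (median -2.54, adjusted p = 3.68e-10), with the lineage regulator gene Zbtb16 at -2.97 ± 0.27 (at least 7.1-fold), Xcl1 at -3.83 ± 0.34 and Il4 as above. B cell markers fell (median -2.33, adjusted p = 8.16e-12), 9 of 12 lower and 0 higher, such as Cd79b (-3.65), Blk (-2.68, at least 4.15-fold) and Fcer2a (-2.33, at least 4.14-fold, another probe -0.79). Dendritic cell markers fell (median -1.76, adjusted p = 1.56e-08), 10 of 13 lower, including H2-Eb1 (-3.38) and H2-Ab1 (-2.71). Macrophage markers (median -1.47, adjusted p = 2.06e-09, 14 of 22 lower and 1 higher, with Sirpa at -3.36) and neutrophil markers (-1.37, 6.10e-06, 5 of 7 lower) fell too. The neutrophil genes were S100a8 (-3.95, detected on 3 infected arrays), Mmp9 (-2.45) and Retnlg (-1.37, at least 1.61-fold). Hepatocyte markers fell (median -1, adjusted p = 0.000201), 4 of 6 lower, with Hp at -2.96 (at least 5.17-fold, other probes -1.01 and -1.37) and Serpina1b at -1.41 (at least 1.90-fold). Of the 24 hepatocyte markers fixed, 18 were below the filter, and Hp and Serpina1b, detected on the 4 naive liver arrays and on 0 of infected liver, passed it through naive liver.

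Not past the threshold in liver were erythroid markers (median log2 -0.01, adjusted p = 0.0637, 0.0375 with the chip as a block and 0.0123 without liver infected 5), plasma cell (-0.08, 0.317) and endothelial markers (0.11, 0.825), T cell identity (0.17, 0.317), follicular helper (-0.12, 0.863), tissue residency (-0.09, 0.602), Th17 (0.09, 0.927), glycolysis (0.28, 0.147), oxidative phosphorylation (0.25, 0.223), cholesterol synthesis (-0.16, 0.317) and ribosomal protein genes (-0.03, 0.436). The test leaned against the median for cytotoxic genes (0.18, adjusted p = 0.521), Th2 genes (0.10, 0.317) and chemokine receptors (-0.14, 0.581). In total 2736 genes changed in liver (1546 higher, 1190 lower), 1479 of them at least 2-fold and 2543 without overlap, and 4287 had an unadjusted p under 0.05. Of all genes, 4126 (31.2%) had groups without overlap, against 1.59% by chance. The count was 4337 with only the liver groups, 5612 with array weights and 4653 with the array score, which kept 2717 of the 2736.

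Rasd2, Serpina12, Miat, Il21 and Ifng rose in both organs, and Aqp9 and Klrk1 fell in both. Across all genes the infection effects of the organs, which share no arrays, correlated at 0.463 (Pearson) and 0.288 (Spearman). Of the called genes, 564 rose in both organs against 100 by independence, 321 fell in both against 80.3, and 69 moved in opposite directions.

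**Figure D2:**
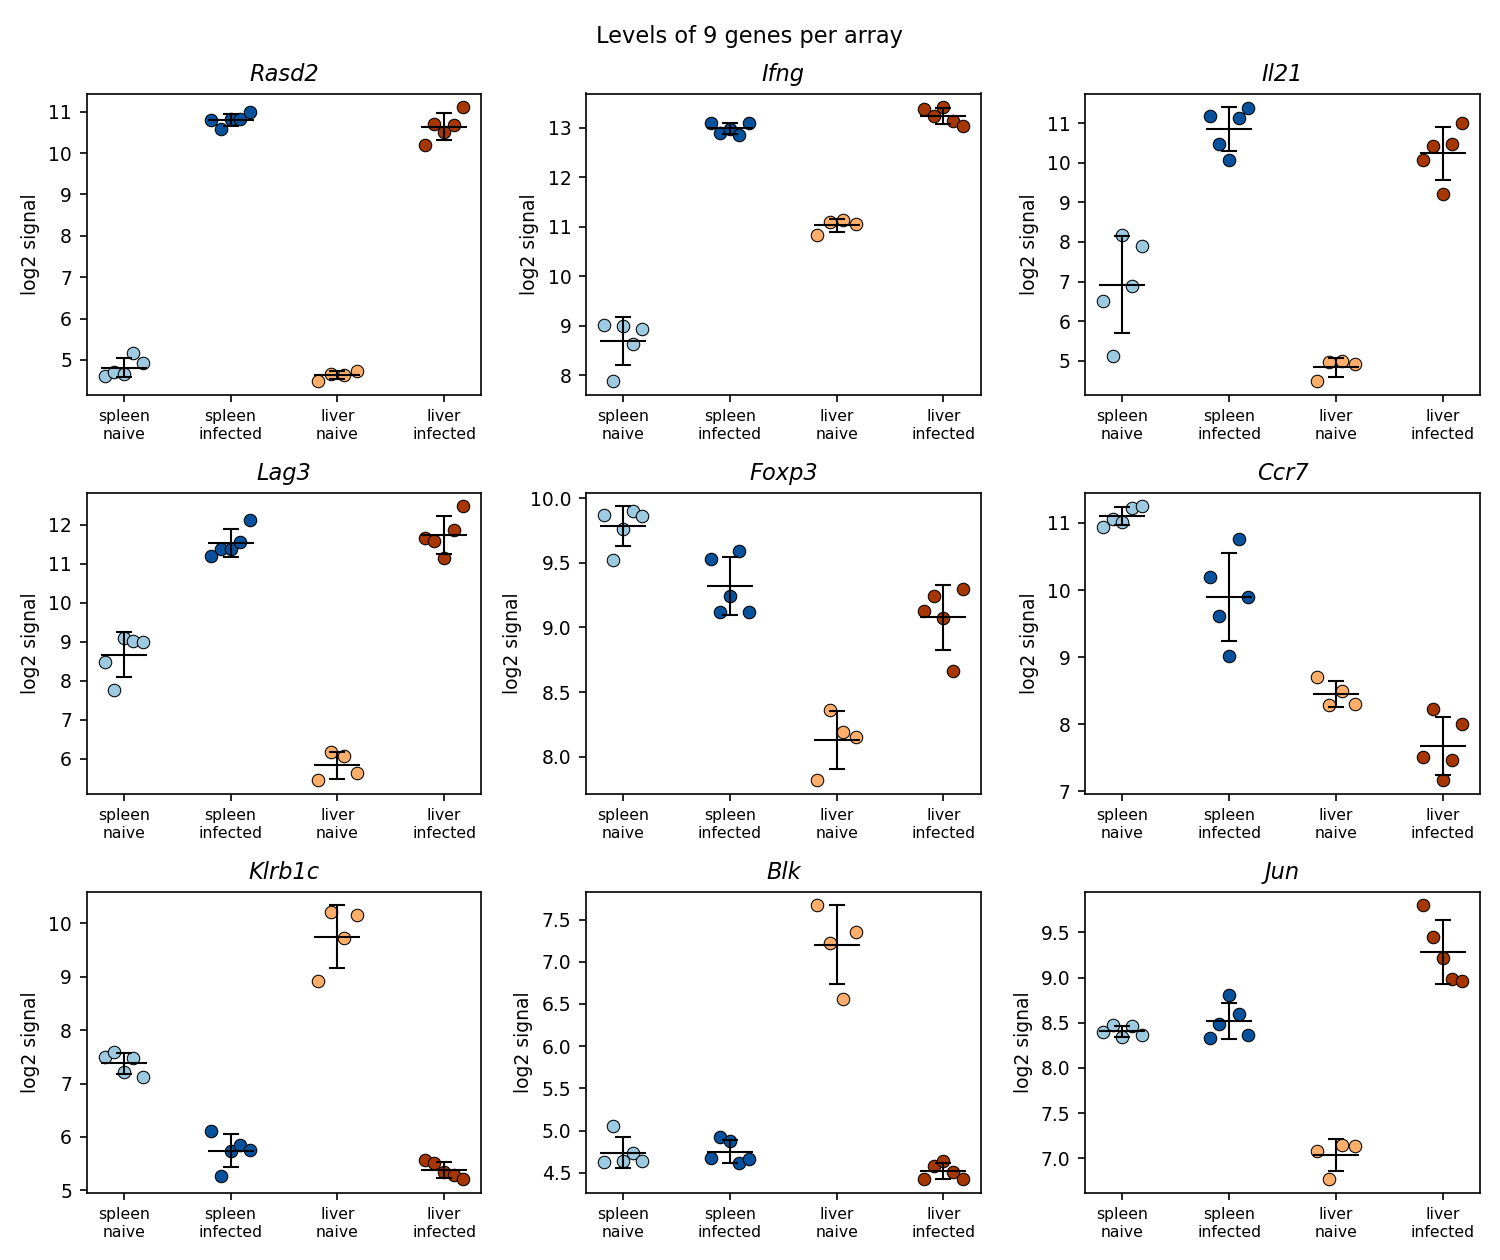
Log2 levels of 9 genes on each array by group, with the mean and SD of the group.

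The infection effect differed between organs for genes of T cell function and of other cell types. The effect was higher in liver than in spleen for Lag3 (log2 difference of the effects 3.06 ± 0.41, adjusted p = 7.55e-05), Foxp3 (1.41 ± 0.22, 0.000452, with -0.46 in spleen and 0.95 in liver), Ctla4 (2.15 ± 0.31, 0.000184) and Tnfrsf4 (2.09 ± 0.28, 8.09e-05). It was lower in liver for Ifng (log2 -2.08 ± 0.27, adjusted p = 4.92e-05), Nkg7 (-2.50 ± 0.49, 0.00302), Cxcr6 (-1.91 ± 0.33, 0.00111), Ccl5 (-1.20 ± 0.18, 0.000281) and the integrin gene Itga1 (-1.98 ± 0.24, 2.50e-05). Ifng, Nkg7, Cxcr6 and Ccl5 were already higher in naive liver than in naive spleen (log2 2.34, 3.66, 2.47 and 1.46). Lag3, Foxp3, Ctla4, Tnfrsf4 and Itgad were lower there (-2.84, -1.65, -1.68, -2.45 and -3.48). Their effects thus do not by themselves show a weaker or stronger response in infected liver. Itga1, Klrc1, Blk, Fcer2a and Hp were at background in both spleen groups and in infected liver, and Klrk1 and Zbtb16 in both infected groups, so their differences of effects follow from the naive groups and measure no difference in response. Itgad in naive liver, Oas2 in infected liver and Ciita in naive spleen and infected liver were also at background, and their differences are given both as fitted and with lower levels raised to the lowest signal of a detected probe. Without the 9 arrays with the fewest detected probes, the calls of Foxp3 (1.16, adjusted p = 0.0631) and Ccl5 (-0.70, 0.144) were lost, and another probe of Foxp3 was at 0.11.

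The largest differences toward liver were Itgad, an integrin gene (log2 3.55 ± 0.31, raised 3.37, adjusted p = 6.68e-07), Crip2 (2.89 ± 0.46, 0.000452), Rgs16, a regulator of G protein signalling (2.73 ± 0.31, 1.61e-05), Galnt9 (2.6 ± 0.50, 0.00243, another probe 0.34) and the histone gene H1f2 (2.52 ± 0.27, 7.66e-06). Toward spleen they were Lyz2 (log2 -5.87 ± 0.62, adjusted p = 6.60e-06, another probe -0.96), Lyz1 (-5.82 ± 0.37, 1.26e-08, other probes -0.77 and -0.68), Hba-a1 (-5.79 ± 0.75, 5.52e-05), H2-Eb1 (-4.93 ± 0.52, 7.28e-06), the chemokine gene Cxcl9 (-4.63 ± 0.28, 8.08e-09) and Hbb-b1 (-4.55 ± 0.65, 0.000184, another probe -1.64). Klf2, a regulator of T cell recirculation, also differed (log2 1.45 ± 0.37, adjusted p = 0.0213), but the call was lost with loess scaling (0.0853), the chip as a block (0.0765) or without liver naive 3 (0.0510).

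Zbtb16 was at the edge of the threshold (log2 -1.25 ± 0.38, adjusted p = 0.0494). Its call was lost with the chip as a block (0.0650), no filter (0.0829), a stricter filter (0.0531), trend and robust moderation (0.0635), and without the 5 (0.161) or 9 (0.189) arrays with the fewest detected probes. It was also lost without spleen naive 1, 2, 3, 4 or 5 (adjusted p = 0.0611, 0.0555, 0.0601, 0.0724 and 0.0711), spleen infected 1, 3, 4 or 5 (0.0735, 0.0724, 0.0700 and 0.0516), liver naive 1, 3 or 4 (0.118, 0.0961 and 0.122) and liver infected 1, 2, 3, 4 or 5 (0.0847, 0.0714, 0.0632, 0.0654 and 0.0739).

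Groups whose infection effect was lower in liver were led by marker genes. They were NK (median log2 -2.45, adjusted p = 1.08e-14, 9 of 11 lower, with Fcer1g at -4.06 and Klrb1c at -2.73), NKT (-2.25, 1.71e-14, 10 of 13), B cell (-2.23, 1.71e-14, 9 of 12, with Blk at -2.69 and Fcer2a at -2.58, another probe -0.66), dendritic (-1.47, 1.24e-14, 9 of 13, with Ciita at -3.97, raised -2.91, another probe -1.32, and H2-Ab1 at -3.80) and macrophage markers (-0.98, 3.03e-09, 7 of 22). Neutrophil (median -1.26, adjusted p = 1.29e-08, 5 of 7, with Mmp9 at -2.77) and plasma cell markers (-0.76, 0.00333, 2 of 5, with Mzb1 at -3.51) followed. The hepatocyte list was called as well (-0.43, 0.00197, 3 of 6, with Hp at -3.31, other probes -0.38 and -1.45), but all 3 members were at background in both spleen groups and in infected liver, so it measures no difference in response. Of the members called lower, 4 of 9 B cell, 3 of 9 NK, 3 of 9 dendritic, 2 of 5 neutrophil, 2 of 7 macrophage and 2 of 10 NKT cell markers were at background in both groups of an organ or in both infected groups. Erythroid markers were also lower (median -0.55, adjusted p = 0.00291, and 0.0597 with an estimated correlation, 2 of 8).

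T cell lists moved in the same comparison. The effect was lower in liver for Th1 effector genes (median log2 -1.36, adjusted p = 1.16e-05, 8 of 20 lower and 2 higher, with Cxcr3 at -1.35) and for genes of the interferon gamma response (-0.60, 4.71e-07, 4 of 27 lower, with Serpina3g at -1.82), tissue residency (-0.72, 1.38e-05, 6 of 17, with Hic1 at -2.17 and Chn2 at -1.22) and cytotoxicity (-0.24, 0.00197, 5 of 16 lower and 1 higher, with Klrk1 at -3.37 and Klrc1 at -3.29). Of the 6 cytotoxic members called, 2 (Klrk1 and Klrc1) were at background in both infected groups. All of these lists were also higher in naive liver than in naive spleen. Their lower effects therefore do not by themselves show a weaker response in infected liver. Effects on type I interferon genes were lower (median -0.45, adjusted p = 0.000433, 2 of 24, with Oas2 at -1.90, raised -1.62), and so were cell cycle genes (-0.47, 0.00105, and 0.154 with an estimated correlation, 1 of 30). The effect was higher in liver for regulatory T cell genes (median 1.02, adjusted p = 0.00291, 4 of 15 higher and 0 lower) and for immediate early and heat shock genes (0.56, 0.0211, and 0.134 with an estimated correlation), whose medians were -0.09 in spleen and 0.57 in liver, 4 of 25 higher and 1 lower, with Jun at 2.14, Fos at 1.95 and Zfp36 at 1.56. The latter call was lost without spleen naive 2 (0.0760) or liver infected 4 (0.0636).

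Not past the threshold in the difference of effects were IL-10 and inhibitory receptor genes (median log2 0.51, adjusted p = 0.232), naive T cell and homing genes (0.52, 0.138), Th17 (-0.53, 0.119), glycolysis (-0.15, 0.305), oxidative phosphorylation (0.22, 0.917), cholesterol synthesis (0.22, 0.591), ribosomal proteins (0.04, 0.776), endothelial markers (-0.06, 0.402) and T cell identity (0.18, 0.620). Naive T cell and homing genes passed with no background correction (adjusted p = 0.00975) and without the 5 (0.00252) or 9 (0.000198) arrays with the fewest detected probes. Chemokine receptor genes passed with no filter (0.0141) and without spleen naive 4 (0.0405), spleen infected 1 (0.0459) or 3 (0.0447) or liver infected 2 (0.0333). The test leaned against the median for follicular helper (0.01, 0.591), chemokine receptor (0.04, 0.0538) and Th2 genes (0.10, 0.305). In all 978 genes differed (460 higher in liver, 518 lower), 748 of them at least 2-fold, with 2841 at an unadjusted p under 0.05. The share of higher genes was 47% and became 35.4% with loess scaling. The count was 3358 with array weights, 2513 with the array score, 626 without the 9 arrays with the fewest detected probes and 1686 without spleen naive 2.

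**Figure D3:**
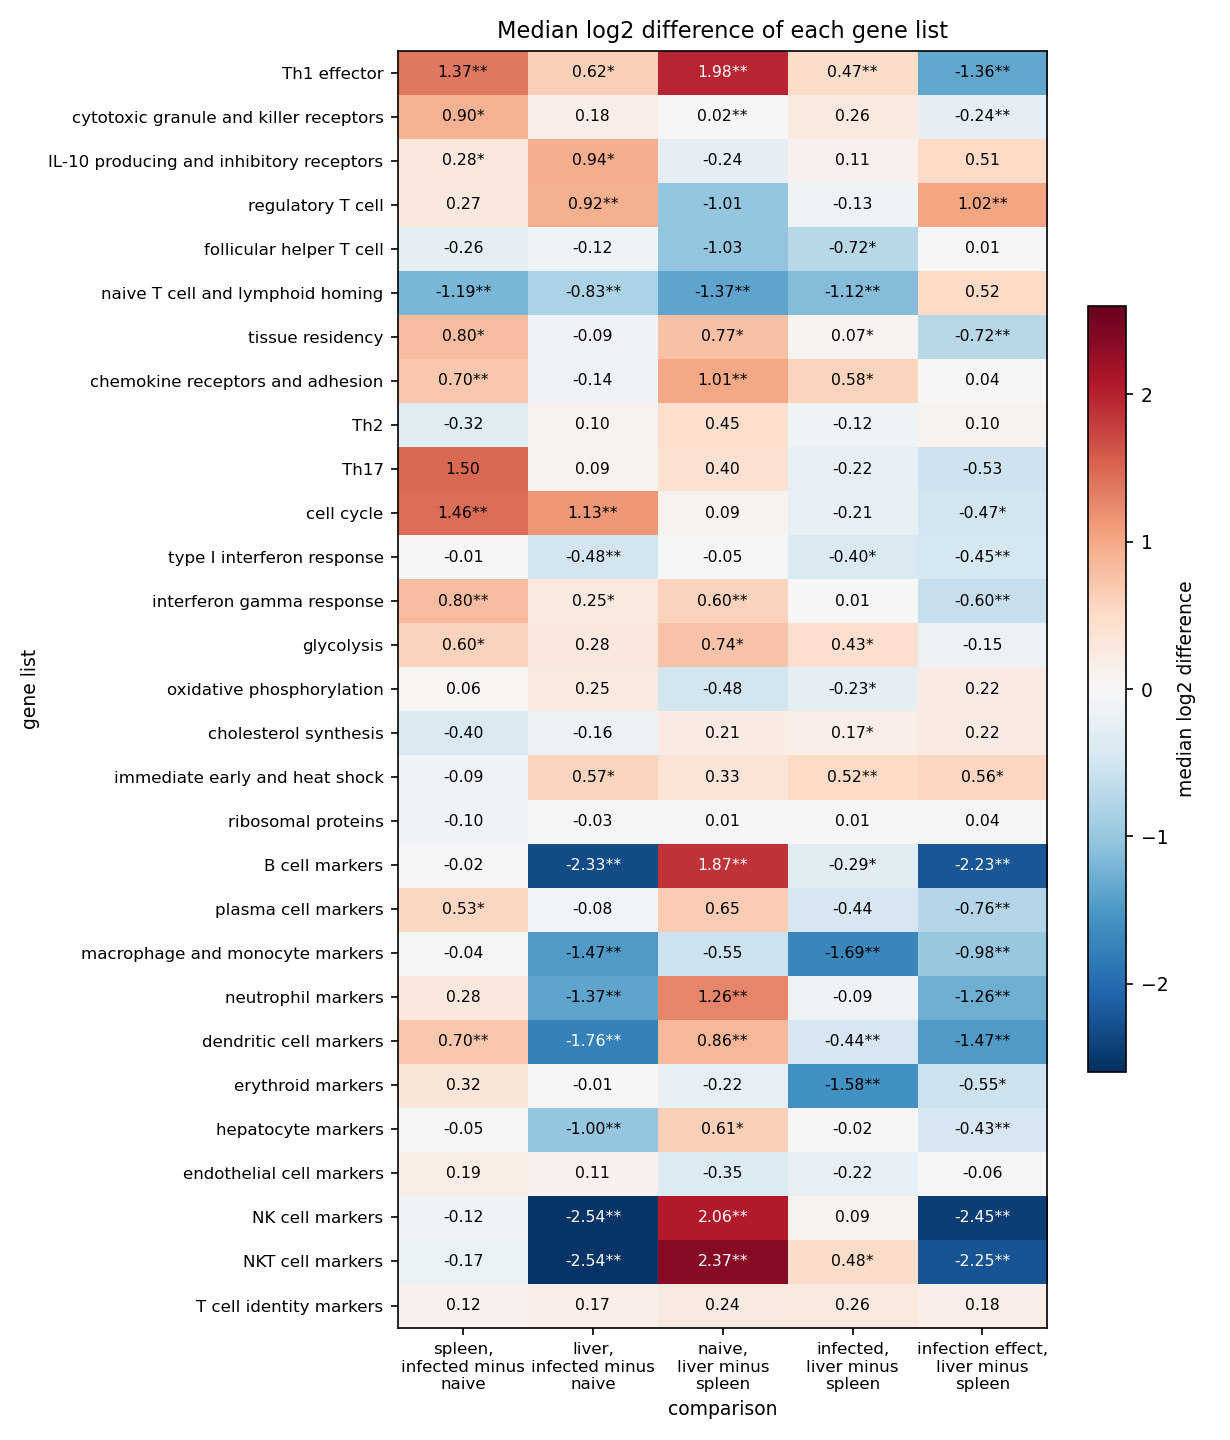
Median log2 difference of each gene list in the 5 comparisons; 1 star marks a camera call, and 2 stars mark a call kept with an estimated correlation.

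Before infection, liver samples were lower than spleen samples in single macrophage genes, Ccr7 and Foxp3. Which cells carried the macrophage genes, here or in infected mice, was not tested. Slc40a1, which encodes the iron exporter ferroportin, was 30.2-fold lower in liver (log2 -4.92 ± 0.34, n = 4 and 5, adjusted p = 1.10e-08), and the adhesion molecule gene Vcam1 25.5-fold lower (-4.67 ± 0.32, 9.24e-09). Foxp3 was 3.14-fold lower (log2 -1.65 ± 0.16, adjusted p = 8.50e-07; other probes -2.82, 0.15 and -2.93). Ccr7 was 6.28-fold lower (log2 -2.65 ± 0.27, adjusted p = 1.30e-06). Cxcr6, a chemokine receptor of liver lymphocytes, was 5.52-fold higher (2.47 ± 0.24, 8.47e-07) and Itga1, a collagen-binding integrin gene, at least 3.26-fold higher (2.53 ± 0.17, 9.24e-09).

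Other genes lower in naive liver were Epb41l3 (at least 12.9-fold, log2 -4.03 ± 0.32, adjusted p = 6.45e-08, another probe -0.47), Slpi (-3.92 ± 0.45, 4.98e-06), Dapl1 (-3.84 ± 0.41, 1.87e-06), the macrophage lectin gene Fcna (-3.71 ± 0.29, 6.12e-08), Itgad (at least 9.91-fold, -3.48 ± 0.22, 5.09e-09) and Cd200 (-3.47 ± 0.50, 5.17e-05, other probes -0.59 and -0.82). Of the 4 naive liver arrays, 3 detected Vcam1, 1 Itgad and 0 Epb41l3. Zbtb16 was 2.43-fold higher (log2 1.28 ± 0.27, adjusted p = 0.00146), and Cd69 was not past the threshold (-0.01 ± 0.16, 0.959), though the mean of its probes was (-0.61, 0.0186). Klf2 was lower (log2 -0.80 ± 0.27, adjusted p = 0.0207), a call lost with loess scaling (-0.51, 0.178) and without liver naive 3 (0.0550), 4 (0.0510) or 5 (0.0523). S1pr1, the receptor for egress from tissue, was at least 1.92-fold lower (log2 -1.40 ± 0.39, adjusted p = 0.00773), a call lost with the array score (-0.24, 0.659) and without the 5 (-0.69, 0.129) or 9 (-0.26, 0.412) arrays with the fewest detected probes.

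Large increases in naive liver moved with the quality of the arrays. B4galnt1 (log2 5.39 ± 1.33, adjusted p = 0.00370), the immunoproteasome gene Psmb8 (5.38 ± 1.48, 0.00701), Actn4 (5.01 ± 1.29, 0.00466), Stip1 (4.89 ± 1.42, 0.00930), Ppp2r1a (4.86 ± 1.20, 0.00366), Hcls1 (4.80 ± 1.11, 0.00245) and Capns1 (4.79 ± 1.35, 0.00786) were past the threshold. With the array score they were at 0.42, 0.14, 0.24, -0.35, 0.74, 0.83 and -0.16, with adjusted p of 0.358, 0.924, 0.682, 0.596, 0.491, 0.245 and 0.842, so Stip1 and Capns1 turned direction. Without the 5 arrays with the fewest detected probes their adjusted p was 0.128, 0.22, 0.159, 0.251, 0.127, 0.0887 and 0.25, and without the 9 with the fewest 0.115, 0.0687, 0.367, 0.705, 0.347, 0.182 and 0.126. Other probes of B4galnt1 (0.22 and 0.08), Psmb8 (2.45) and Actn4 (2.49) moved less. Naive liver detected more probes (mean 17718, SD 210, n = 4) than naive spleen (13995, SD 1470, n = 5, exact permutation p = 0.0159, adjusted p = 0.127). Infected liver had 15704 (SD 1190) and was lower by 2013 than naive liver (exact permutation p = 0.0238, adjusted p = 0.127), and infected spleen 14750 (SD 1850). The array score follows this order, and its first component holds 72.9% of the variance of probe deviations.

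**Figure D4:**
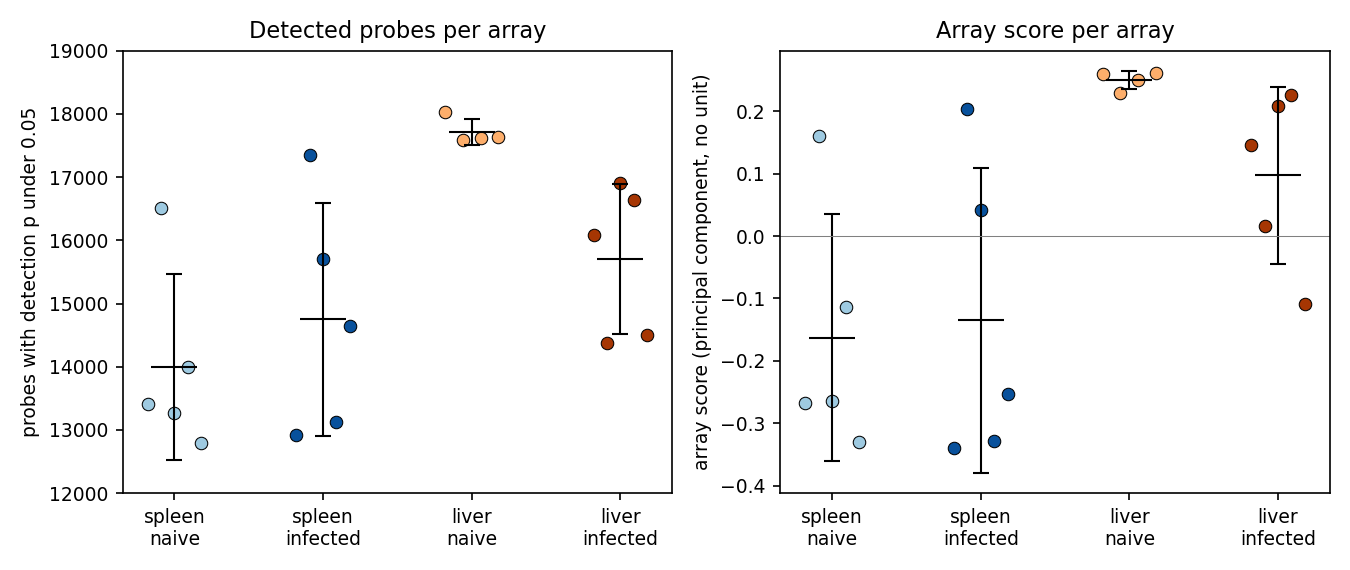
Number of detected probes and array score of each array by group, with the mean and SD of the group.

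**Figure D5:**
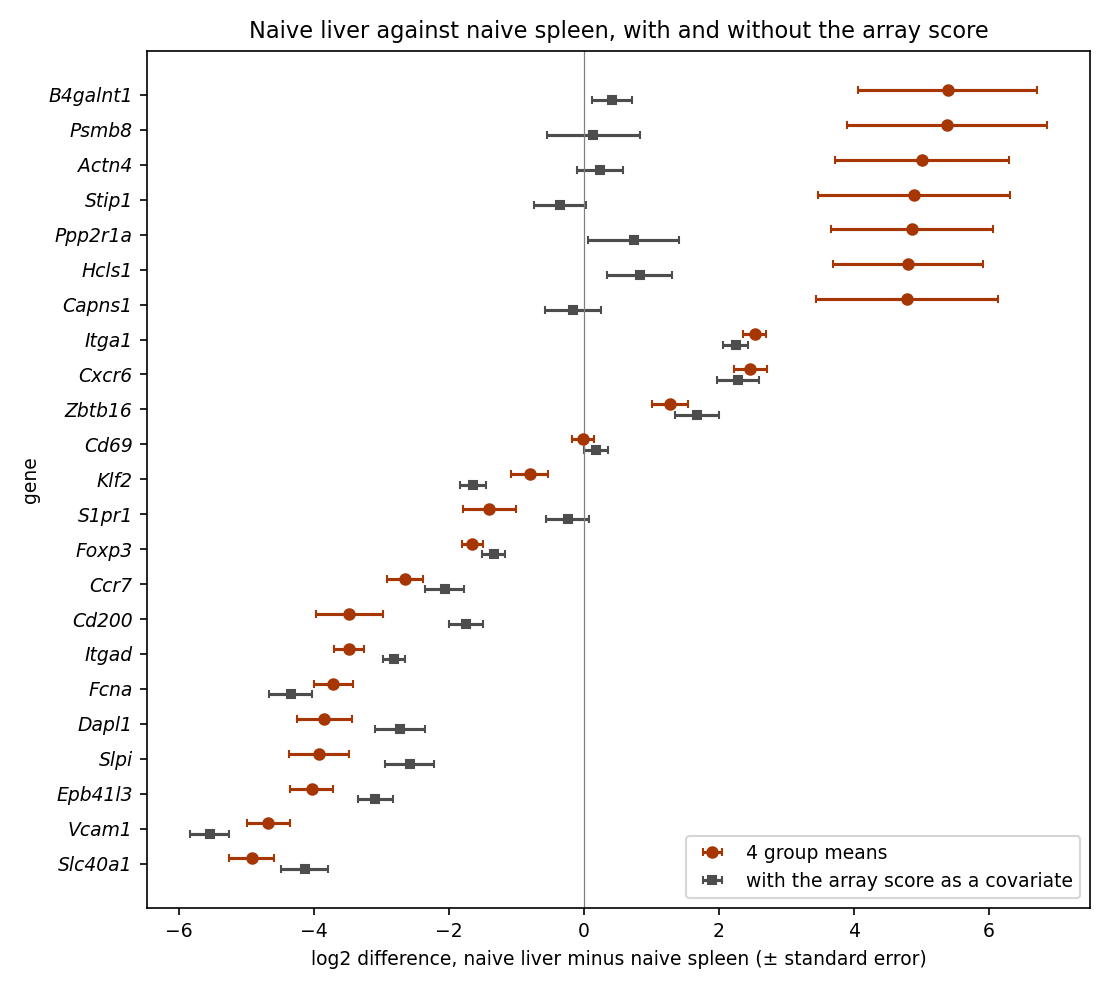
Log2 difference between naive liver and naive spleen for 23 genes, with its standard error, from the group means and with the array score as a covariate.

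Effector and innate-like groups were higher in naive liver with and without the array score. All 13 NKT cell markers were higher (median log2 2.37, adjusted p = 3.59e-11), and 10 of 11 NK cell markers (2.06, 3.57e-08) were higher, such as Klre1 (4.47) and Klrb1c (2.37). Th1 effector genes were higher (median 1.98, adjusted p = 2.12e-06), 15 of 20 higher and 5 lower, including Ifng (2.34), Cxcr3 (1.62) and Ccl5 (1.46). Cytotoxic genes were higher by the test (adjusted p = 0.00483) with a median of 0.02, 6 of 16 higher and 3 lower, led by Klrk1 (3.72), Nkg7 (3.66) and Klrc1 (3.17, at least 5.23-fold). Interferon gamma response genes (0.60, 2.77e-05, 16 of 27 higher and 1 lower, with Serpina3g at 1.83) and chemokine receptors (1.01, 0.0127, 10 of 18 higher and 4 lower) were higher as well. Tissue residency genes were higher (median 0.77, adjusted p = 5.05e-05, and 0.0503 with an estimated correlation), 10 of 17 higher and 3 lower, with Hic1 at 2.42 and Chn2 at 2.08. Naive T cell and homing genes were lower (median -1.37, adjusted p = 4.79e-05), 15 of 20 lower and 0 higher, among them Dapl1 and Sox4 (-2.43, another probe -0.16).

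Markers of other cell types were also higher in naive liver. They were B cell (median log2 1.87, adjusted p = 2.12e-06, 8 of 12 higher, with Blk at 2.46, at least 3.4-fold, detected on 1 naive spleen array, and Fcer2a at 2.37, at least 3.4-fold, another probe 0.57), neutrophil (1.26, 9.17e-05, 6 of 7, with Mmp9 at 3.83 and Retnlg at 1.26, at least 1.33-fold) and dendritic cell markers (0.86, 9.61e-06, 8 of 13, with H2-Eb1 at 3.46 and Ciita at 2.32, at least 3.11-fold, another probe 0.34). Hepatocyte markers were higher (median 0.61, adjusted p = 0.00891, and 0.0669 with an estimated correlation), 4 of 6 higher and 1 lower, with Hp at 2.95 (at least 4.25-fold, other probes 0.67 and 1.39). Glycolysis genes were higher (median 0.74, adjusted p = 0.0204, and 0.420 with an estimated correlation), 7 of 18 higher and 3 lower, with Slc2a3 at 1.16. With the array score their median was -0.17 (camera of limma, adjusted p = 0.689), and leaving out the 5 or 9 arrays with the fewest detected probes gave an adjusted p of 0.0731 or 0.248.

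Regulatory T cell genes, 8 of 15 lower and 2 higher in naive liver (median log2 -1.01, adjusted p = 0.0507), passed the threshold with the chip as a block (0.0449), the array score (0.000306), no filter (0.00483) and without the 5 arrays with the fewest detected probes (0.00966). They also passed without spleen naive 1 (0.0351), 3 (0.0412) or 5 (0.0288), spleen infected 5 (0.0439), liver naive 1 (0.0415), 3 (0.0399) or 4 (0.0394) or liver infected 1 (0.0491) or 4 (0.0466). Not past it were IL-10 and inhibitory receptor (-0.24, 0.692), follicular helper (-1.03, 0.343), Th2 (0.45, 0.337), Th17 (0.40, 0.165), cell cycle (0.09, 0.0757, and 0.0188 without liver naive 4), oxidative phosphorylation (-0.48, 0.243), cholesterol synthesis (0.21, 0.473), immediate early (0.33, 0.250) and ribosomal genes (0.01, 0.876). Type I interferon genes had a median of -0.05 with a test leaning to higher values (adjusted p = 0.386). Plasma cell (0.65, 0.165), macrophage (-0.55, 0.761), erythroid (-0.22, 0.522), endothelial (-0.35, 0.709) and T cell identity genes (0.24, 0.503) were not past it either.

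In all 6676 genes differed between naive organs (2503 higher in liver, 4173 lower), 3789 of them at least 2-fold and 4845 without overlap, and 7667 had an unadjusted p under 0.05. Of all genes, 5156 (39%) had groups without overlap, against 1.59% by chance. With the array score 2742 differed, of which 1698 were shared with the 6676 in the same direction and 23 in the opposite direction. Without the 5 or 9 arrays with the fewest detected probes 2163 or 1763 differed. The median of all genes was -0.224 in this comparison, -0.123 with loess scaling, -0.1 without background correction and -0.085 with the authors' matrix. The share of higher genes among those called was 37.5%, and 45.2% with loess scaling, 37.7% without background correction and 36.5% with the authors' matrix.

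Between infected organs, single stress and activation genes were higher in liver and Slc40a1 and Hbb-b1 were lower. Hspa1a, which encodes an inducible heat shock protein, was 8.71-fold higher in liver (log2 3.12 ± 0.40, n = 5 and 5, adjusted p = 7.70e-05; other probes 1.74 and 0.68). It was already 8.51-fold higher in naive liver (log2 3.09 ± 0.43, n = 4 and 5, adjusted p = 3.49e-05; other probes 1.53 and 0.18). The stress gene Gadd45b was 4.42-fold higher (2.14 ± 0.28, 0.000103; another probe 0.59), and the activator protein genes Fosb and Junb 4.40-fold (2.14 ± 0.35, 0.000877) and 3.43-fold higher (1.78 ± 0.32, 0.00205). Slc40a1 was 30.6-fold lower (log2 -4.94 ± 0.32, adjusted p = 2.31e-08), the beta-globin gene Hbb-b1 22.7-fold lower (-4.51 ± 0.45, 4.17e-06) and the ubiquitin-like gene Ubd 22-fold lower (-4.46 ± 0.27, 1.26e-08).

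Also lower in infected liver were the Fc receptor gene Fcgr4 (log2 -4.04 ± 0.39, adjusted p = 3.45e-06), Epb41l3 (at least 9.28-fold, -3.92 ± 0.30, 1.90e-07, another probe -0.64), Ear2 (at least 10-fold, -3.60 ± 0.32, 1.03e-06, another probe -1.52), Sirpa (-3.52 ± 0.25, 4.41e-08) and Hba-a1 (-3.51 ± 0.51, 0.000268). Ccr7 (log2 -2.22 ± 0.26, adjusted p = 2.35e-05) stayed lower in liver. Cxcr6 (0.56 ± 0.23, 0.131), S1pr1 (-0.76 ± 0.37, 0.177), Klf2 (0.65 ± 0.25, 0.121), Zbtb16 (0.02 ± 0.26, 0.955) and Foxp3 (-0.24 ± 0.15, 0.287) were not past the threshold. Zbtb16 and Itga1 were at background in both infected groups, which leaves their difference there unmeasured. Itga1 (0.56 ± 0.16, 0.0531) and Cd69 (0.50 ± 0.15, 0.0566) were just short of it, and Cd69 passed it with loess scaling (0.0185), the authors' matrix (0.0292), the array score (0.0176), a stricter filter (0.0462), trend and robust moderation (0.0325) and array weights (0.00405). It also passed without the 5 (0.0291) or 9 (0.0272) arrays with the fewest detected probes, spleen naive 2 (0.0488) or 5 (0.0489) or spleen infected 1 (0.0167) or 2 (0.0424). With array weights Itga1 (0.000693), Klf2 (0.00103) and S1pr1 (0.00484) passed. Leaving out spleen naive 2 (0.0404), spleen infected 2 (0.0189) or liver infected 5 (0.00687) passed Itga1, and leaving out spleen infected 2 passed Klf2 (0.0330).

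Aktip was higher in infected liver (log2 1.87 ± 0.35, adjusted p = 0.00313), whereas calls of 3 other genes leaned on single arrays. Itgb1 (log2 1.90 ± 0.45, adjusted p = 0.0190) was lost with the chip as a block (0.0962), the array score (0.0705), only the infected groups (0.0685) and without spleen infected 1 (0.0652), 4 (0.0668) or 5 (0.0569) or liver infected 4 (0.0639). Phlda3 (1.96 ± 0.49, 0.0240) was lost with the chip as a block (0.0848), the array score (0.0669), no filter (0.0521) and only the infected groups (0.144). It was also lost without spleen infected 1 (0.0726), 4 (0.0806) or 5 (0.0566) or liver infected 1 (0.0554), 3 (0.0675) or 4 (0.0531). Susd3 (1.86 ± 0.49, 0.0319, another probe 0.49) was lost with the chip as a block (0.0955), the array score (0.123), no filter (0.0669) and only the infected groups (0.124). It was also lost without spleen infected 1 (0.102), 4 (0.106) or 5 (0.0725) or liver infected 1 (0.0659), 2 (0.0638), 3 (0.0680) or 4 (0.0622). Without the 5 or 9 arrays with the fewest detected probes, Itgb1 (0.182 and 0.259), Phlda3 (0.201 and 0.18) and Susd3 (0.105 and 0.295) were lost too.

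The stress genes moved as a group. Immediate early and heat shock genes were higher in infected liver (median log2 0.52, adjusted p = 2.53e-07), 8 of 25 higher and 0 lower, including Tnfaip3 (1.10), and 14 adjusted over the list alone. Naive T cell and homing genes stayed lower (median -1.12, adjusted p = 2.87e-07, 9 of 20 lower and 0 higher), with Sox4 at -1.62 (at least 2.23-fold, another probe 0.56, mean of its probes -0.53, adjusted p = 0.0962). Macrophage markers were lower (median -1.69, adjusted p = 2.52e-14), 12 of 22 lower and 0 higher, such as Spic (-2.86, at least 4.54-fold), a regulator of iron-recycling macrophages. Erythroid markers (-1.58, 1.59e-05, 4 of 8 lower, with Blvrb at -2.47) and dendritic cell markers (-0.44, 0.000636, 4 of 13 lower, with H2-Aa at -3.31 and Ciita at -1.65, at least 2.42-fold) were lower with them. Th1 effector genes were higher (median 0.47, adjusted p = 0.000636), 1 of 20 past the threshold and 6 adjusted over the list alone. The 1 gene was Il18rap (2.08, adjusted p = 0.0455), whose call was lost when any of 15 of the 19 arrays was left out (0.0530 to 0.148) and with the chip as a block (0.141), only the infected groups (0.181), the array score (0.160), no filter (0.0953), the mean of its probes (0.0543) and without the 5 (0.492) or 9 (0.366) arrays with the fewest detected probes.

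Follicular helper genes were lower in infected liver (median log2 -0.72, adjusted p = 0.00741, and 0.175 with an estimated correlation), 7 of 14 lower and 0 higher. Cxcr5, the receptor that guides cells to B cell follicles, was 7.09-fold lower (log2 -2.83 ± 0.30, adjusted p = 1.05e-05, another probe -0.60), Id3 3.43-fold lower (-1.78 ± 0.32, 0.00228) and the lineage regulator gene Bcl6 1.77-fold lower (-0.82 ± 0.16, 0.00328). Type I interferon genes were lower (median -0.40, adjusted p = 0.0315, and 0.175 with an estimated correlation), 7 of 24 lower and 0 higher, with Oasl2 at -2.65, Usp18 at -1.90 (another probe -0.05) and Oas2 at -1.67 (at least 2.62-fold). Their call was lost without spleen infected 2 (0.142) or 3 (0.0659) or liver infected 2 (0.0543) or 5 (0.1).

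Further list calls between infected organs were lost with an estimated correlation. Glycolysis genes (median log2 0.43, adjusted p = 0.0127, 0 of 18 past alone, and 0.335 with an estimated correlation) lost their call with the array score (0.846), without the 5 arrays with the fewest detected probes (0.647) and without spleen infected 1 (0.0681). B cell markers (-0.29, 0.0371, 2 of 12 lower, with Cd22 at -2.13, another probe -0.05, and 0.175 with an estimated correlation) lost it with the authors' matrix (0.0505), no background correction (0.0624), without the 9 arrays with the fewest detected probes (0.0804) and without spleen infected 2 (0.104) or liver infected 2 (0.0543) or 5 (0.0888). Chemokine receptors (0.58, 0.0460, 1 of 18 higher and 2 lower, and 0.0918 with an estimated correlation) lost it without spleen infected 2 (0.0676) or 3 (0.0838) or liver infected 2 (0.0688), 4 (0.0501) or 5 (0.0787). Cholesterol synthesis (0.17, 0.0460, 0 of 18 past alone, and 0.0918 with an estimated correlation) lost it with the array score (0.189), without the 5 arrays with the fewest detected probes (0.101) and without spleen infected 2 (0.0676), 3 (0.0651) or 4 (0.0537) or liver infected 2 (0.0543) or 5 (0.0777).

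Oxidative phosphorylation genes (median log2 -0.23, adjusted p = 0.0460, 1 of 27 lower, and 0.477 with an estimated correlation) lost their call with loess scaling (0.134), the array score (0.0912) and without spleen naive 2 (0.0564), spleen infected 2 (0.0727) or 3 (0.0750) or liver infected 2 (0.0543), 3 (0.0547) or 4 (0.0811). NKT cell markers (0.48, 0.0460, 0 of 13 past alone, and 0.109 with an estimated correlation) lost it without spleen naive 2 (0.0545), spleen infected 2 (0.162) or 3 (0.0654) or liver infected 2 (0.0543), 3 (0.0738) or 5 (0.0909). Tissue residency genes (0.07, 0.0476, and 0.335 with an estimated correlation), of which only Chn2 (0.85) passed alone among 17, lost it with fry (0.103) and the authors' matrix (0.0849). They also lost it without spleen naive 1 (0.0512), 2 (0.0673), 4 (0.0506) or 5 (0.0522), spleen infected 2 (0.198) or 3 (0.141) or liver infected 2 (0.0596), 4 (0.0515) or 5 (0.0909).

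Not past the threshold between infected organs were cytotoxic (median log2 0.26, adjusted p = 0.0541), IL-10 and inhibitory receptor (0.11, 0.559), cell cycle (-0.21, 0.320), interferon gamma response (0.01, 0.559), ribosomal (0.01, 0.682), plasma cell (-0.44, 0.222), neutrophil (-0.09, 0.712), endothelial (-0.22, 0.118) and T cell identity genes (0.26, 0.0621). Cell cycle genes were called with the array score (adjusted p = 0.000562), without the 5 (0.000133) or 9 (3.06e-08) arrays with the fewest detected probes and without spleen infected 4 (0.0391). Cytotoxic genes were called with the authors' matrix (0.0365), no background correction (0.0484), no filter (0.0198), without the 5 arrays (0.0427) and without spleen infected 1 (0.0379) or 3 (0.0427) or liver infected 1 (0.0468) or 4 (0.0472). The test leaned against the median for regulatory T cell (-0.13, 0.903), Th2 (-0.12, 0.712), Th17 (-0.22, 0.593), hepatocyte (-0.02, 0.674) and NK cell genes (0.09, 0.674). In total 732 genes differed (206 higher in liver, 526 lower), 424 of them at least 2-fold and 443 without overlap, and 3896 had an unadjusted p under 0.05. Of all genes, 634 (4.8%) had groups without overlap, against 0.794% by chance. The organ differences of naive and infected mice correlated at 0.725 (Pearson) and 0.727 (Spearman), and the cause of this agreement was not tested. Of the called genes, 104 were higher in both against 39 by independence, 338 lower in both against 166.2, and 55 opposite.

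The count between infected organs was the least stable. It was 348 with the chip as a block, 271 with only the infected groups, 277 and 383 without the 5 and 9 arrays with the fewest detected probes, and 7528 with array weights. Without single arrays it was 1123 (spleen naive 2), 357, 4241, 1332, 379 and 395 (spleen infected 1 to 5), and 429, 474, 382, 389 and 1283 (liver infected 1 to 5).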

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

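The values of 1698 shared genes, 0.034 for Hspa1a and 1.38e-12 for the immediate early genes come from tests chosen after the results were seen, as do the array score and the sets without 5 or 9 arrays.

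More genes differed between naive liver and naive spleen (6676) than in the other 4 comparisons, and naive liver had the best arrays. That group alone is labelled as pools (of 5 mice), so effects of pooling cannot be separated from it. If array quality were the whole cause, few calls would stay with the array score, but 1698 (25.4%) stayed in the same direction. The score did not overlap between these groups (below), so this cannot exclude quality as the whole cause. The score ended 4955 calls, whose median size went from 1.02 to 0.23 and standard error from 0.29 to 0.21. Among genes with another detected probe, the other probes moved under 50% as much as the tested probe, or the opposite way, in 60.3% of 1800 genes whose call ended and in 54% of 569 genes whose call stayed. They moved the opposite way in 713 and 160 of these, and the median ratio to the tested probe was 0.25 and 0.41. All lean toward quality, but the shares differ by less than the ratio of 1.5 set beforehand, so whether quality caused the ended calls stays open. A true difference in RNA content between liver and spleen T cells is a biological explanation that was not tested.

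Markers of NK, NKT and B cells, such as Klrb1c, Zbtb16 and Blk, were high in naive liver and fell with infection there. With the array score the largest adjusted p of the 3 lists was 1.03e-10 (camera). The score did not overlap between naive liver (0.23 to 0.261) and naive spleen (-0.33 to 0.161), so this cannot exclude quality. Cells of other types in the sorted samples predict that B cell and neutrophil markers stay higher with the score, which was met (largest adjusted p 2.55e-06). NKT cells among the CD4+ cells of naive liver are a biological explanation that was not tested. NKT cells do not make B cell or neutrophil markers, so the result for these 2 lists argues against them as the source of the B cell markers. For the NK and NKT cell markers both explanations stay open, and which cells carried the markers was not tested. Of other genes, looked up after the values were seen, Alb, Fabp1 and Ncr1 were detected on 0 arrays, and Apoa1, Ttr and Runx3 on 2, 1 and 3 arrays, all of naive liver. Cd8a was detected on 0 arrays but Cd8b1 on all 19, at group means of log2 11.09 to 11.46, so CD8 T cells are not excluded.

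Immediate early and heat shock genes, such as Hspa1a, Fosb and Junb, were higher in infected liver than in infected spleen. The adjusted p (camera) was 1.38e-12 with the array score, which argues against quality as the whole cause, as far as the score measures it. An organ preparation that acts alike in naive and infected mice predicts no difference of the infection effects, and the adjusted p of that difference was 0.00801 with the score, which argues against it as the whole cause. With an estimated correlation that value was 0.172, so the argument is weak. For Hspa1a such a preparation stays open, because the difference of its infection effects was 0.034 (log2), with 3.09 between naive and 3.12 between infected organs. Stimulation of the cells in the infected liver is a biological explanation that was not tested.

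Among 100 splits of the arrays, the real grouping included, 3 called as many genes as infection in spleen (real 1026, highest other 4633), 1 as infection in liver (4337, 3812), 1 as naive organs (6857, 0), 3 as infected organs (271, 6255) and 4 as the difference of the effects (978, 6029). In liver infection and naive organs no other drawn split called as many genes, which argues against chance. Yet their real splits ranked 5 and 1 by gap in array score, which these counts cannot be separated from. In the other comparisons the share was under 5%, but other splits called more genes, so these counts cannot exclude chance. Splits calling several times the real count point to a structure of the samples. In spleen infection, liver infection and infected organs the other split with the highest count had the largest gap in array score.

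Single arrays stood apart from the rest of their group in 4 of 16 array measures, against 0.8 by chance. They were liver naive 1 for detected probes (18031), liver naive 4 for median signal (179.3) and spread (2.48), and spleen naive 2 for spread (2.68). For named genes 28 of 406 groups (6.9%) held such an array, against 20.3 groups by chance. It was most often spleen naive 2 (6 times), then liver infected 1 and liver naive 1 (4 times each).

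In spleen naive 2 the genes were Actn4 (log2 9.73), Blk (5.06), Cxcr3 (10.50), Hcls1 (8.39), Klre1 (6.03) and Ppp2r1a (9.95). In other spleen samples they were Lilr4b in naive 1 (4.75), Ttc28 in naive 3 (9.07), Aqp9 and Cxcr3 in infected 1 (5.78 and 12.41), Itga1 in infected 2 (4.73) and Il10 in infected 5 (7.88). In naive liver they were Chn2, Dapl1, Klf2 and Oasl1 in sample 1 (9.63, 7.46, 12.35 and 6.68) and Actn4 in sample 5 (10.51). In infected liver they were Cd22, Klrc1, S1pr1 and Serpina1b in sample 1 (5.55, 4.65, 4.94 and 4.88), Sox4 in 2 (5.04), Adgrg5 and H2-Ab1 in 3 (8.15 and 9.43), Itgb1 in 4 (8.41), and Klf2, Klrg1 and Tpx2 in 5 (12.51, 10.16 and 7.4).

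The infection effect differed between liver and spleen for 978 genes. As given above, the values of Itga1, Klrc1, Blk, Fcer2a, Hp, Klrk1 and Zbtb16 follow from the naive groups because of background levels. With background levels raised as above, Itgad, Oas2 and Ciita were at 3.37, -1.62 and -2.91. Differing naive levels limit the values of Lag3, Foxp3, Ctla4, Tnfrsf4, Itgad, Ifng, Nkg7, Cxcr6 and Ccl5 as described above. Higher in liver were Itgad (log2 3.55), Lag3 (3.06), Crip2 (2.89), Rgs16 (2.73), Galnt9 (2.6), H1f2 (2.52), Ctla4 (2.15), Jun (2.14), Tnfrsf4 (2.09), Fos (1.95), Zfp36 (1.56), Klf2 (1.45) and Foxp3 (1.41). Lower in liver, by up to log2 -2.50, were Ccl5 (-1.20), Chn2 (-1.22), Zbtb16 (-1.25), Cxcr3 (-1.35), Serpina3g (-1.82), Oas2 (-1.90), Cxcr6 (-1.91), Itga1 (-1.98), Ifng (-2.08), Hic1 (-2.17) and Nkg7 (-2.50). Lower by more were Fcer2a (-2.58), Blk (-2.69), Klrb1c (-2.73), Mmp9 (-2.77), Klrc1 (-3.29), Hp (-3.31), Klrk1 (-3.37), Mzb1 (-3.51), H2-Ab1 (-3.80), Ciita (-3.97), Fcer1g (-4.06), Hbb-b1 (-4.55), Cxcl9 (-4.63), H2-Eb1 (-4.93), Hba-a1 (-5.79), Lyz1 (-5.82) and Lyz2 (-5.87).

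List medians of the same difference were 1.02 for regulatory T cell, 0.56 for immediate early and heat shock, -0.24 for cytotoxic, -0.43 for hepatocyte (whose 3 called members were at background in both spleen groups and in infected liver), -0.45 for type I interferon, -0.47 for cell cycle, -0.55 for erythroid, -0.60 for interferon gamma, -0.72 for residency and -0.76 for plasma cell genes. They were -0.98 for macrophage, -1.26 for neutrophil, -1.36 for Th1, -1.47 for dendritic cell, -2.23 for B cell, -2.25 for NKT cell and -2.45 for NK cell genes.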

How the results depend on the processing

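The array score and the sets without 5 or 9 arrays were chosen after seeing the data. Counts that moved by over 1.5 times were, for infection in spleen (1745 genes), 3215 with array weights, 3773 with the array score and 1026 with only the groups compared. For infection in liver (2736) they were 5612, 4653 and 4337. Between naive organs (6676) they were 2742 with the array score, 2163 without the 5 arrays and 1763 without the 9. Between infected organs (732) they were 348 with the chip as a block, 7528 with array weights, 277 and 383 without the 5 and 9 arrays and 271 with only the groups compared. For the difference of the effects (978) they were 3358 with array weights, 2513 with the array score and 626 without the 9 arrays, and the share of genes higher in liver went from 47% to 37% without the 5 arrays, 29.4% without the 9, 59.7% with a stricter filter and 62.2% with array weights. The called lists went from 11 to 6 with an estimated correlation and to 18 with fry in spleen infection, from 13 to 24 with fry between naive organs and from 15 to 6 with an estimated correlation between infected organs. The cause was not tested for any of these shifts. Turned directions were found for Capns1 (log2 -0.16), Stip1 (-0.35) and glycolysis genes (adjusted p = 0.689) between naive organs with the array score, and for ribosomal protein genes there with fry (0.00216).

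Leaving out each array in turn gave 1455 to 2104 genes for infection in spleen, 2111 to 3135 for infection in liver, 5521 to 7965 for naive organs, 357 (spleen infected 1) to 4241 (spleen infected 2) for infected organs and 707 to 1686 (spleen naive 2) for the difference of the effects. It gave 10 to 12, 14 to 16, 13 to 15, 8 to 16 and 16 to 18 called lists in the same order, with 8 without spleen infected 2 or liver infected 2 and 9 without liver infected 5 between infected organs. The correlation of the infection effects, 0.463, went from 0.329 to 0.548 over left-out arrays and from 0.429 to 0.538 over other settings. Of 221 called gene results, all 221 stayed with array weights and with no background correction, 218 with loess scaling, 213 with the chip as a block, 209 with the array score, 205 without the 5 arrays and 202 without the 9. Of 71 called list results, 71 stayed with the chip as a block and no filter, 70 with loess scaling, 68 with fry, 67 with the array score, 68 without the 5 arrays, 66 without the 9 and 47 with an estimated correlation.

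No label says that the sample numbers pair the samples, and the titles and descriptions of naive liver number them differently. Deviations of same-numbered samples correlated at -0.54 to 0.91 between naive and infected spleen and at -0.24 to 0.06 between naive and infected liver, and at -0.15 to 0.24 between naive and -0.52 to 0.54 between infected spleen and liver. Samples correlated best with their own number in 2 of 5, 1 of 4, 1 of 4 and 2 of 5 cases. With the replicate block the counts were 1770, 3182, 7490, 1096 and 1122 genes, all 221 called gene results stayed, and 7 of 71 list calls were lost. Those were, in liver infection, Th1 (adjusted p = 0.0685) and interferon gamma genes (0.0640), and between infected organs residency (0.0730), chemokine receptor (0.0510), oxidative phosphorylation (0.0535), cholesterol synthesis (0.0510) and NKT cell genes (0.0535). The block passed Ccr7 in liver infection (0.0398), Itga1 between infected organs (0.0469) and chemokine receptor genes in the difference of the effects (0.0459), and changed no other call of the genes and lists named. A block by description number ended 1 gene call, Zbtb16 in the difference of the effects (0.0695), and a block within status ended 2 calls, that one (0.0624) and Il18rap between infected organs (0.0624).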

Other observations

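Cytokine genes and inhibitory receptor genes rose in the same infected groups. Ifng, Il21, Il10, Lag3 and Havcr2 rose in both organs. Only Lag3 among these had a larger effect in liver past the threshold (log2 3.06 ± 0.41), from a lower naive level there (-2.84). Whether the same cells expressed them was not tested. The rise of Il10 in spleen was lost without the 5 (adjusted p = 0.143) or 9 (0.0816) arrays with the fewest detected probes. Foxp3, 3.14-fold lower in naive liver than in naive spleen, no longer differed past the threshold between infected organs (log2 -0.24 ± 0.15, adjusted p = 0.287), after it had risen in liver.

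Klrk1 was 13.2-fold higher in naive liver than in naive spleen (log2 3.72 ± 0.18) and fell with infection to background in both organs, in liver by at least 31.9-fold (log2 -5.37 ± 0.18) and in spleen by at least 2.29-fold. It was detected on 2 of 5 infected liver arrays and on 0 of 5 of infected spleen, so its contrast between infected organs was not measured. Klrg1, another killer receptor gene, was 3.74-fold higher in infected liver than in infected spleen (log2 1.90 ± 0.43, adjusted p = 0.0142), a call lost with the chip as a block (0.0729), with only the infected groups (0.103), without the 5 arrays with the fewest detected probes (0.184) and without spleen infected 1 (0.0526) or 4 (0.0517). Slc40a1 was lower in liver in naive (log2 -4.92 ± 0.34) and infected mice (-4.94 ± 0.32).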
